A study of Mus musculus with 9 samples.

How the data were processed

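Gene expression was measured in 9 liver tumors of C57BL/6 mice aged 11 weeks, with 3 tumors in each of the groups LHP, S7HP and S7HP+Snail. Per the labels' protocols, RNA was taken with Trizol, and QuantSeq libraries were made from 500 ng of total RNA. QuantSeq reads start near the 3′ end of polyadenylated transcripts, so each transcript gives about 1 read whatever its length. Per the submitters' processing notes, Bowtie2, edgeR and the build mm10 were used, with no versions or roles given. The counting tool and the annotation are not given in the sources used here.

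Each deposited file gives 1 value per gene symbol for 1 tumor, over 24421 symbols. The deposited values are log2 of a quantile-normalized read count plus 1, as the values themselves show. The 9 files share their highest value and have totals between 19910396 and 19911234, with differences among the lowest values, where many genes are tied. In each file 9 times the unlogged value is a whole number for 100% of values, as the mean of 9 libraries' counts at the same rank would give. The tolerance was 0.001 for small values and widened in proportion for larger ones, so the largest values passed in any case. The mean total over the 9 libraries was 19910797 normalized counts, and the total count of each library is not preserved. Steps between the lowest values still give relative depths, estimated at 0.767, 0.826 and 0.945 for LHP tumors 2, 3 and 6, at 0.814, 0.563 and 0.977 for S7HP tumors 9, 11 and 12, and at 1.38, 1.88 and 0.822 for S7HP+Snail tumors 13, 14 and 15. A total of 3 reads corresponded to a log2 value between 1.22 and 2.64 depending on the library. Both estimates take successive lowest values as successive read counts. That is not certain, since the value of rank 12 above 0 held more genes than ranks 11 and 13 in 9 of 9 libraries. The ribosomal transcript Rn45s ranked first in 9 of 9 libraries, at 5.50% of the counts. Mitochondrially encoded symbols were not among those analysed here.

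The design assumed raw counts. Because the files hold normalized log2 values, the fallback fixed before the data were examined was used. Genes with a log2 value of at least 4 in at least 3 libraries were kept (14215 genes), a filter set once the unit was known and before any test result was seen. All 9 libraries were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and with eBayes using an intensity trend and robust variances, leaving 6 residual degrees of freedom. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are differences of mean log2(normalized count + 1), which understate the changes of genes near 0. Standard errors (SE) are limma's, and SD is over the 3 tumors of a group. The labels do not say whether the tumors came from separate animals, so p-values measure the spread between these samples.

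Gene lists for pathways and cell types were fixed before the data were examined, with 563 of 578 entries matched to a symbol, older symbols included, and 29 lists were tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists of a comparison, and again with an estimated correlation and with fry. Counts of called list members are given over all genes and adjusted over the list alone. The genes named are Smad7, Snai1, Hras and Trp53, the 8 rising and 8 falling genes with the largest change per comparison, and up to 4 called members per list with the smallest adjusted p. Genes named outside that rule are said to be so, and a few genes are not reported here. A gene in the second set had to be called, to have no overlap between the groups and to have a mean log2 value of at least 7.32, and predicted genes were passed over. Coordinates come from GENCODE mouse release 21 on GRCm38, the assembly that mm10 names, and 95.5% of symbols matched 1 GENCODE gene.

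The procedure was tested on simulated data for S7HP against LHP over 14215 genes, of which 200 were changed. It called 4%, 60%, 84% and 94% of the genes changed by 1, 2, 3 and 5 on the log2 scale, with 5 calls among 14015 unchanged genes. For S7HP+Snail against S7HP there were 10 calls among 14015 unchanged genes. The adjusted threshold depends on how many genes change, so the shares called hold for 200 changed genes only. Alternatives were another scaling, filter, variance model and choice of libraries in the fit, and each library was left out in turn. Count-based tests were not run, since the deposited values are not counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.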

Results

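The data set holds 3′ expression profiles of 9 mouse liver tumors, 3 each from the groups LHP, S7HP and S7HP+Snail. The series addresses an oncogenic route from TGF-β through Smad proteins to Snail. Column names in the files tie LHP to a Luc construct and S7HP to Smad7, the inhibitory Smad that blocks TGF-β receptor signaling. The added Snail is the transcription factor encoded by Snai1, which represses epithelial genes. Each library holds 24421 gene symbols, and the mean total was 19910797 normalized counts. On the first principal component (40.1% of the variance) LHP tumors lay between -106.4 and -89.1, S7HP tumors between 60.3 and 91.2, and S7HP+Snail tumors between 16 and 27.2. S7HP+Snail tumor 14 stood apart on the second component (18.6%) at 118.1, against 31.3 and 25.9 for tumors 13 and 15. Correlations across the tested genes, which are not independent replicates, were 0.939 to 0.945 within LHP, 0.923 to 0.936 within S7HP and 0.864 to 0.900 within S7HP+Snail.

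**Figure D1:**
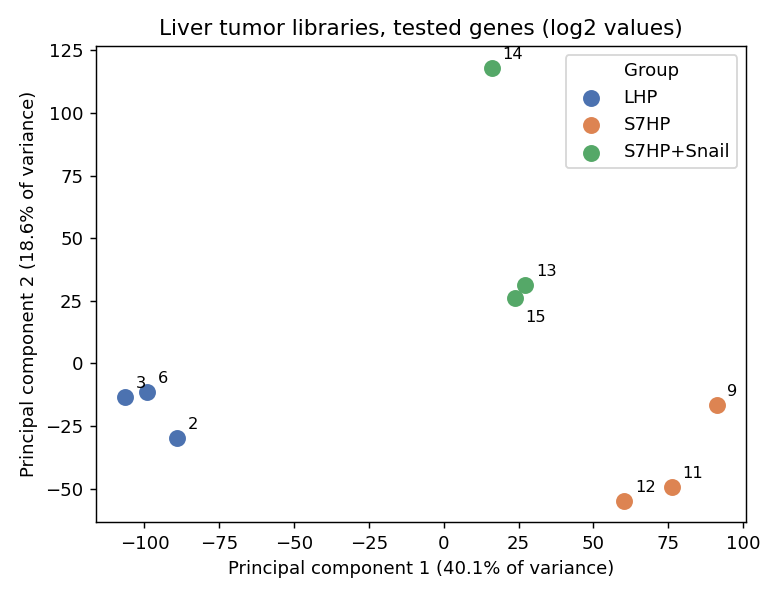
Scores of the 9 tumor libraries on principal components 1 and 2 of the log2 values of the tested genes, with each point a tumor labelled by its number and colored by group. The 3 groups separate on the first axis, and S7HP+Snail tumor 14 lies at 118.1 on the second.

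Smad7 was not higher in the tumors named for it. Its log2 value (GRCm38 chromosome 18, 75367529 to 75395935) was 10.07 ± 0.52 in LHP, 6.52 ± 0.27 in S7HP and 7.36 ± 0.62 in S7HP+Snail (SD, n = 3 each). Snai1 (chromosome 2, 167538195 to 167542814) was at 10.69 ± 0.66 in LHP, 6.48 ± 0.39 in S7HP and 8.10 ± 0.69 in S7HP+Snail (SD, n = 3 each). Relative to LHP, Smad7 fell by 3.55 ± 0.38 (SE) and Snai1 fell by 4.22 ± 0.43 in S7HP (limma, Benjamini-Hochberg adjusted p = 0.000691 and 0.000613). With Snail added, Snai1 was higher than in S7HP by 1.63 ± 0.43, in 3 of 3 tumors, which did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.085). Hras (chromosome 7, 141189105 to 141194005) had group means of 10.09, 10.67 and 9.90, and Trp53 (chromosome 11, 69580359 to 69591873) had means of 6.37, 6.25 and 5.53, in the order LHP, S7HP and S7HP+Snail. Neither gene was called in any comparison. A 3′ tag counts a construct for the mouse gene only if the construct carries that gene's 3′ end, which the labels do not state, so these values do not check the labels.

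**Figure D2:**
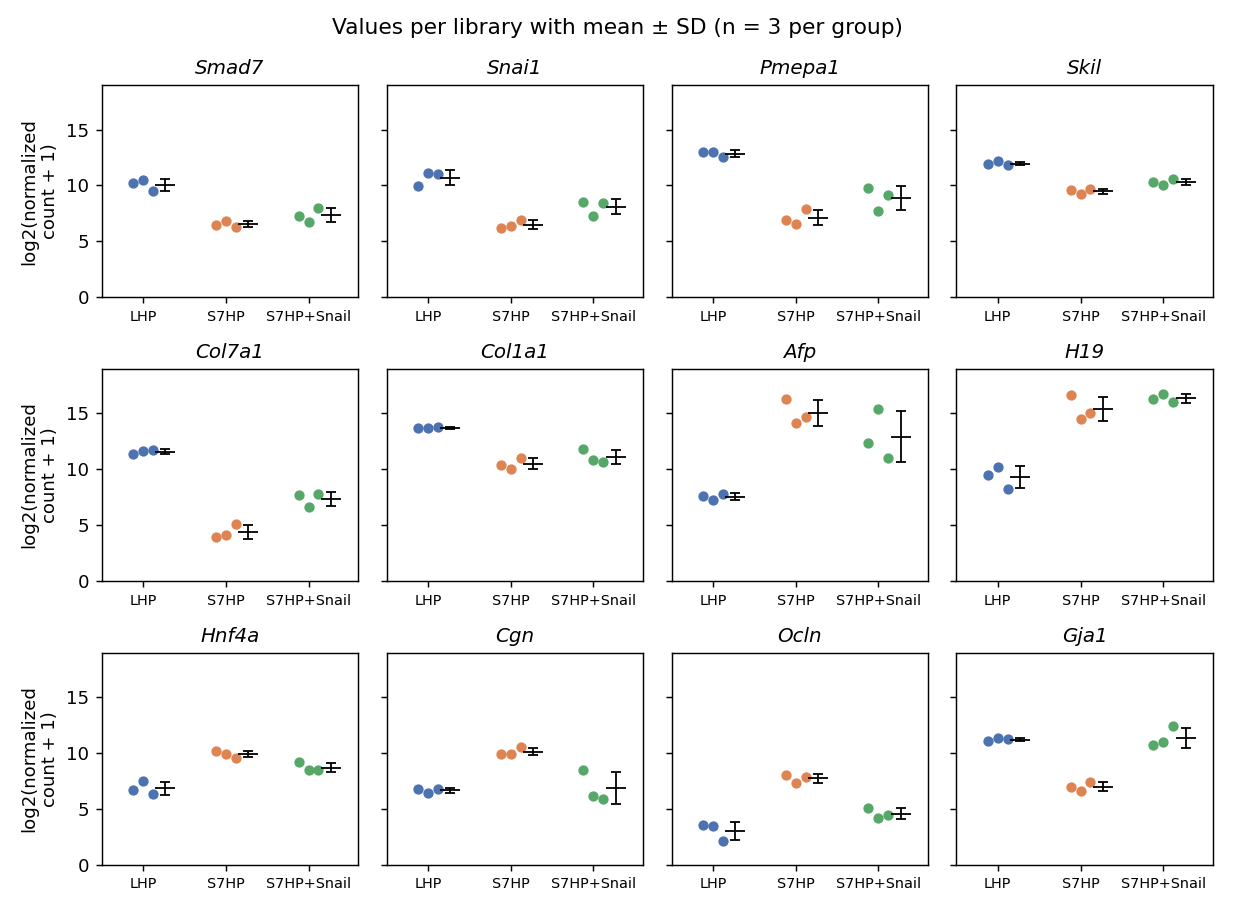
Log2(normalized count + 1) of 12 genes in the 3 tumors of each group, with points for tumors and a black bar for the mean ± SD. Smad7, Snai1, Pmepa1, Skil, Col7a1 and Col1a1 are highest in LHP, while Afp, H19 and Hnf4a are lowest there.

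The comparison of S7HP with LHP asks what differs when Smad7 takes the place of the Luc construct. In S7HP, 22 of 25 matrix genes, 12 of 20 mesenchymal genes and 9 of 25 TGF-β target genes fell, and 12 of 25 hepatocyte, 6 of 12 fetal liver, 9 of 25 epithelial junction and 10 of 22 interferon response genes rose. Against these directions, 1 TGF-β target gene rose and 1 fetal liver gene fell. These 7 lists passed limma camera with a preset correlation but not with an estimated one (Benjamini-Hochberg adjusted p = 0.142 to adjusted p = 0.501 with an estimated correlation). Tff1, a secreted trefoil peptide, rose by 8.80 ± 1.08 (SE) on the log2 scale, and Afp, the fetal liver protein alpha-fetoprotein, rose by 7.49 ± 0.96, from 7.55 ± 0.30 to 15.04 ± 1.14 (SD, n = 3 each). Col7a1, the anchoring fibril collagen, fell by 7.20 ± 0.41, from 11.59 ± 0.20 to 4.40 ± 0.65. Adjusted p was 0.0012, 0.00147 and 4.01e-05 for these 3 genes (limma, Benjamini-Hochberg). Of 14215 genes, 2702 were called, 1346 higher and 1356 lower, and 1224 of them changed more than 4-fold.

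The other genes with the largest rises were the glutathione transferases Gsta1 (6.67) and Gsta4 (6.22), the hormone gene Apela (6.29), Calml4 (6.26), the trypsin inhibitor Spink1 (6.23) and the imprinted RNA H19 (6.05). Gsta1 has near-identical copies that may share its reads, and Apela was listed at 0 in 1 LHP tumor. The deepest falls after Col7a1 were in the mechanosensitive channel Piezo2 (-5.91), the TGF-β-induced membrane protein Pmepa1 (-5.73), podoplanin, Pdpn (-5.61), cardiac troponin T, Tnnt2 (-5.58), the chemokine receptor Ackr3 (-5.34), fibulin 2, Fbln2 (-5.17), and urokinase, Plau (-5.01).

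Of 25 extracellular matrix genes, 22 fell, 0 rose and 3 did not pass (0 rose and 23 fell when adjusted over the list alone). Col5a1 fell by 3.89, Col1a1 by 3.19 and the laminin gene Lamb1 by 3.27 (log2 changes -3.89, -3.19 and -3.27). The list fell as a whole (limma camera, Benjamini-Hochberg adjusted p = 5.85e-12, and adjusted p = 0.272 with an estimated correlation). Of 20 mesenchymal genes, 12 fell, 0 rose and 8 did not pass (15 fell when adjusted over the list alone), among them the transcription factors Prrx1 (-4.22), Zeb2 (-2.17) and Foxc2 (-4.05). The mesenchymal list passed at an adjusted p of 1.84e-07 (limma camera, Benjamini-Hochberg), with adjusted p = 0.142 with an estimated correlation. Markers of other cell types moved alongside. The stellate cell and fibroblast list fell, with 6 of 17 members lower, 0 higher and 11 not passing (7 lower and 1 higher when adjusted over the list alone), including Acta2 (-3.02) and Pdgfrb (-2.64), at a Benjamini-Hochberg adjusted p of 0.000371 (limma camera; adjusted p = 0.272 with an estimated correlation). Of the endothelial list, 3 of 18 fell and 0 rose (2 fell when adjusted over the list alone), and of the macrophage list 2 of 19 fell and 0 rose (also 2 when adjusted over the list alone). Both lists had a Benjamini-Hochberg adjusted p of 0.0126 (limma camera), with adjusted p = 0.589 and adjusted p = 0.501 with an estimated correlation. Without S7HP tumor 12 the endothelial list no longer passed, at 0.0518 in a leave-one-out range of 0.000132 to 0.0518 (limma camera, Benjamini-Hochberg adjusted p).

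Among 25 TGF-β and Smad target genes, 9 fell, 1 rose and 15 did not pass (11 fell and 1 rose when adjusted over the list alone). Pmepa1, the transcriptional corepressor Skil (-2.48 ± 0.22, SE), the activin antagonist Fstl3 (-2.61) and the matrix protein gene Tgfbi (-1.76) were the falls with the smallest adjusted p. The list fell at a Benjamini-Hochberg adjusted p of 0.000371 (limma camera; adjusted p = 0.501 with an estimated correlation). The member that rose, named after its value was seen, was Id2 (1.70), an inhibitor of helix-loop-helix factors, whose call was lost without LHP tumor 2 or 6 or S7HP tumor 9 or 12 (limma, Benjamini-Hochberg adjusted p up to 0.0858). Of 19 TGF-β ligands, receptors and Smads, 6 fell and 0 rose (7 fell and 2 rose when adjusted over the list alone), led by the activin subunit Inhba (-4.84). That list had a Benjamini-Hochberg adjusted p of 0.0294 (limma camera; adjusted p = 0.501 with an estimated correlation), and it no longer passed without LHP tumor 3 or S7HP tumor 11, at up to 0.0868.

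Hepatocyte genes rose, with 12 of 25 higher, 0 lower and 13 not passing (14 higher when adjusted over the list alone). The transcription factor Hnf4a rose by 3.05, retinol binding protein Rbp4 by 2.90 and Ambp by 2.52, while Cyp2e1, chosen after its value was seen, was at 0.18 ± 0.76 (SE) without passing. The list had a Benjamini-Hochberg adjusted p of 1.39e-07 (limma camera; adjusted p = 0.501 with an estimated correlation). Of 12 fetal liver genes, 6 rose, 1 fell and 5 did not pass (6 rose and 2 fell when adjusted over the list alone), including Igf2 (5.85) and Gpc3 (3.42), at a Benjamini-Hochberg adjusted p of 0.0373 (limma camera; adjusted p = 0.501 with an estimated correlation). The fetal list no longer passed without LHP tumor 2 or S7HP tumor 12, at up to 0.0618. Of 25 epithelial junction genes, 9 rose, 0 fell and 16 did not pass (10 rose when adjusted over the list alone), among them occludin, Ocln (4.69), cingulin, Cgn (3.48), and connexin 32, Gjb1 (2.55), at a Benjamini-Hochberg adjusted p of 4.98e-05 (limma camera; adjusted p = 0.501 with an estimated correlation). Alongside, of 16 biliary and progenitor markers 4 rose, 2 fell and 10 did not pass (5 rose and 2 fell when adjusted over the list alone), with Tspan8 at 5.09, Prom1 at 4.77, Onecut1 at 3.85 and Sox9 at -1.87. That list had a Benjamini-Hochberg adjusted p of 0.0432 (limma camera; adjusted p = 0.577 with an estimated correlation), and it no longer passed without LHP tumor 3, S7HP tumor 9 or 12 or S7HP+Snail tumor 15 (up to 0.121). The call of Sox9 was lost without LHP tumor 2 or 3 or S7HP tumor 11 (limma, Benjamini-Hochberg adjusted p up to 0.0722). Of 22 interferon response genes, 10 rose, 0 fell and 12 did not pass (14 rose when adjusted over the list alone), with Usp18 at 3.47 and Irf7 at 1.67, at a Benjamini-Hochberg adjusted p of 3.48e-06 (limma camera; adjusted p = 0.501 with an estimated correlation). Of 30 cell cycle genes, 0 rose and 1 fell, the transcription factor E2f1 (-1.60), and the list did not pass, at an adjusted p of 0.0853 that ran from 0.000108 to 0.698 when 1 library was left out (limma camera, Benjamini-Hochberg). The erythroid list was higher alongside, with 1 of 7 members risen and 0 fallen (the same when adjusted over the list alone), at a Benjamini-Hochberg adjusted p of 0.0483 (limma camera; adjusted p = 0.644 with an estimated correlation). It no longer passed without LHP tumor 6, S7HP tumor 9 or 12 or S7HP+Snail tumor 14 (up to 0.186), and 2 of its members, the alpha globin genes Hba-a1 and Hba-a2, are near-identical copies. The lists of fatty acid oxidation, of urea and amino acid genes and of bile acid and xenobiotic genes were higher, with 5 of 20, 4 of 20 and 6 of 19 members risen and 0 fallen in each (6, 4 and 6 when adjusted over the list alone), at Benjamini-Hochberg adjusted p of 0.000371, 0.00361 and 0.00351 (limma camera; adjusted p = 0.554, adjusted p = 0.612 and adjusted p = 0.589 with an estimated correlation). The RAS output list was lower, with 1 of 21 members risen and 1 fallen (the same when adjusted over the list alone), at a Benjamini-Hochberg adjusted p of 0.0493 (limma camera; adjusted p = 0.548 with an estimated correlation). Without S7HP tumor 9 the urea and amino acid list no longer passed (0.0868), nor did the RAS output list without LHP tumor 2 or 3 or S7HP tumor 9 or 11 (up to 0.189). The groups did not overlap for 42.1% of the genes, against a chance share of 10%. The count of 2702 moved with single libraries, to 1479 and 1465 without LHP tumors 3 and 6 and to 1594 and 1768 without S7HP tumors 9 and 11, and it was 3430 when only the 6 libraries compared were fitted.

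**Figure D3:**
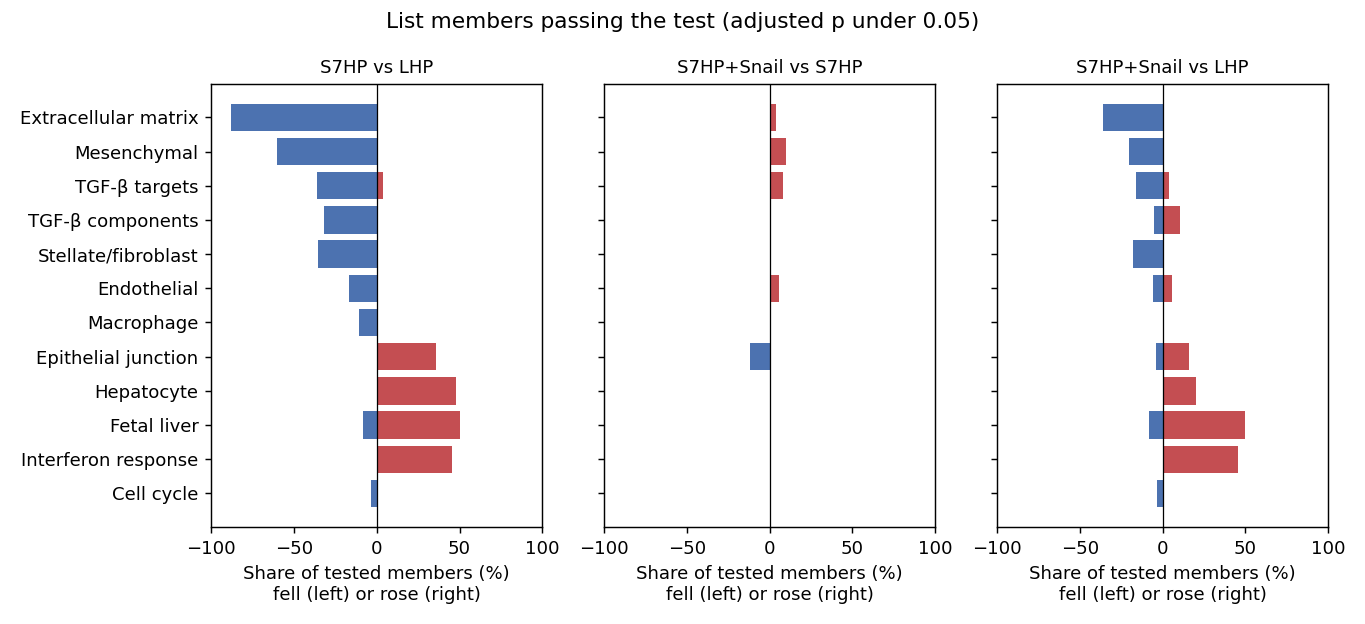
Share of the tested members of 12 gene lists that rose (red, right of 0) or fell (blue, left of 0) at an adjusted p under 0.05 in each of the 3 comparisons. In S7HP against LHP, 22 of 25 matrix genes fell and 12 of 25 hepatocyte genes rose.

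The comparison of S7HP+Snail with S7HP asks what the Snail construct adds. With Snail, 3 of 25 epithelial junction genes fell, and 2 of 20 mesenchymal genes and 1 of 25 matrix genes rose. The 3 lists passed limma camera with a preset correlation but not with an estimated one (Benjamini-Hochberg, adjusted p = 0.526 with an estimated correlation for each). Nr2f1, a nuclear receptor transcription factor, rose by 5.58 ± 0.69 (SE), from 4.64 ± 0.24 to 10.22 ± 0.94, and connexin 43, Gja1, rose by 4.38 ± 0.41, from 7.01 ± 0.40 to 11.40 ± 0.90 (SD, n = 3 each). Plakophilin 2, Pkp2, a desmosomal protein, fell by 3.41 ± 0.30, from 9.17 ± 0.25 to 5.76 ± 0.43. Their adjusted p was 0.00578, 0.00277 and 0.00277 (limma, Benjamini-Hochberg). Of 14215 genes, 327 were called, 143 higher and 184 lower, and 211 of them changed more than 4-fold.

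Other large rises were in the lysophospholipase Enpp2 (5.10), Igfbp5 (4.54), Crispld2 (4.48), Nrep (4.25), the sulfotransferase Chst2 (4.05) and Tgfb1i1, a TGF-β-induced focal adhesion protein (3.73). The other falls were in Tff1 (-5.17), Clic6 (-4.74), Sprr1a (-4.34), the potassium channel subunit Kcnab1 (-4.29), the kinesin Kif5c (-3.85), Sox11 (-3.77) and Tuft1 (-3.33). Without S7HP tumor 11 or 12 the calls of Enpp2, Clic6, Sprr1a and Kcnab1 were lost, and those of Tgfb1i1 and Kif5c without S7HP tumor 9 as well, with adjusted p up to 0.0952 (limma, Benjamini-Hochberg). Crispld2 was lost without S7HP tumor 9, 11 or 12 or S7HP+Snail tumor 13 or 15 (up to 0.119), and Sox11 without LHP tumor 3 or 6 or S7HP tumor 9, 11 or 12 (up to 0.1). The fall of Tff1 was lost in 11 of 17 alternatives, among them leaving out any 1 LHP or S7HP tumor or S7HP+Snail tumor 15, with adjusted p between 0.0104 and 0.13 (limma, Benjamini-Hochberg).

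Of 25 epithelial junction genes, 3 fell, 0 rose and 22 did not pass (9 fell when adjusted over the list alone): Pkp2, Ocln (-3.16) and Cgn (-3.30). E-cadherin, Cdh1, chosen after its value was seen, was at -2.47 ± 0.77 (SE) without passing. The S7HP+Snail tumors differed, with Cdh1 at 14.17, 10.54 and 11.28 in tumors 13, 14 and 15, against 14.26, 14.18 and 14.95 in S7HP. The list fell (limma camera, Benjamini-Hochberg adjusted p = 5.08e-06, and adjusted p = 0.526 with an estimated correlation). Of 20 mesenchymal genes, 2 rose, Tcf4 (2.74) and the protease Mmp9 (2.79), and 0 fell (6 rose when adjusted over the list alone). The mesenchymal list had a Benjamini-Hochberg adjusted p of 0.000283 (limma camera; adjusted p = 0.526 with an estimated correlation). Of 25 matrix genes, Lamb1 alone rose (2.54) and 0 fell (5 rose when adjusted over the list alone), at a Benjamini-Hochberg adjusted p of 5.16e-05 for the list (limma camera; adjusted p = 0.526 with an estimated correlation). Among the TGF-β targets, 2 of 25 rose, Tgfbi (2.57) and thrombospondin 1, Thbs1 (2.18), and 0 fell (5 rose and 1 fell when adjusted over the list alone), at a Benjamini-Hochberg adjusted p of 0.0427 (limma camera; adjusted p = 0.808 with an estimated correlation). Alongside, the endothelial list rose with 1 of 18 members called, Plvap (1.45), and 7 when adjusted over the list alone, at a Benjamini-Hochberg adjusted p of 7.37e-05 (limma camera; adjusted p = 0.526 with an estimated correlation). The macrophage list was higher with 0 of 19 members called by limma, also when adjusted over the list alone, and 2 higher at an unadjusted p under 0.05, at a Benjamini-Hochberg adjusted p of 0.00574 (limma camera; adjusted p = 0.526 with an estimated correlation). The hepatocyte list was lower, with 0 of 25 members called by limma (4 lower when adjusted over the list alone, and 10 lower at an unadjusted p under 0.05), at a Benjamini-Hochberg adjusted p of 5.16e-05 (limma camera; adjusted p = 0.66 with an estimated correlation). The calls of Ocln and Cgn were lost without S7HP tumor 9, 11 or 12, that of Tcf4 without 11 or 12 and that of Lamb1 without 11, with adjusted p up to 0.0887 (limma, Benjamini-Hochberg). Mmp9 was lost without LHP tumor 2, any 1 S7HP tumor or S7HP+Snail tumor 14 or 15, and Thbs1 and Plvap without any 1 LHP or S7HP tumor or S7HP+Snail tumor 13 or 14, with adjusted p up to 0.152, 0.143 and 0.13 (limma, Benjamini-Hochberg). The TGF-β target list no longer passed without S7HP tumor 11 or S7HP+Snail tumor 15 (up to 0.311), and the macrophage list without S7HP+Snail tumor 14 (0.0512). The list of TGF-β ligands, receptors and Smads was higher with 0 of 19 members called by limma (5 higher when adjusted over the list alone, and 5 at an unadjusted p under 0.05), at a Benjamini-Hochberg adjusted p of 0.0066 (limma camera; adjusted p = 0.526 with an estimated correlation). Lower lists were glycolysis and hypoxia (0 of 22 members called by limma, 6 lower at an unadjusted p under 0.05), cholesterol synthesis (0 of 20, 9 lower), fatty acid synthesis (1 of 19 fallen), fatty acid oxidation (1 of 20 fallen) and the urea and amino acid list (1 of 20 fallen), with 0, 3, 2, 1 and 1 lower when adjusted over each list alone. Their Benjamini-Hochberg adjusted p was 0.00136, 0.000459, 0.0179, 0.0188 and 0.0475 (limma camera; adjusted p = 0.808, adjusted p = 0.526, adjusted p = 0.558, adjusted p = 0.808 and adjusted p = 0.862 with an estimated correlation). All but the cholesterol list of these 6 lost their call when a single library was left out. The count of 327 fell to 136, 63 and 87 without S7HP tumors 9, 11 and 12, to 205 and 187 without LHP tumors 3 and 6, and to 120 when only the 6 libraries compared were fitted. The balance of directions turned without an S7HP tumor, to 78 higher and 58 lower, 36 and 27, and 57 and 30 without tumors 9, 11 and 12. The groups did not overlap for 20.5% of the genes, against a chance share of 10%, and without S7HP+Snail tumor 14 the count was 310, with 214 genes shared with the 327.

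Of the 327 genes called with Snail, 243 (74.3%) had been called in the opposite direction in S7HP against LHP, with 138 that rose in S7HP and fell with Snail and 105 that fell and then rose. Tff1, Pkp2, Ocln and Cgn were among the former, and Gja1, Mmp9, Lamb1 and Tcf4 among the latter. Acsl6 and Lrp8, named after their values were seen, were the 2 called in the same direction, lower at each step. Both were fragile: Lrp8 was lost in 8 and 9 of 17 alternatives in the 2 comparisons and Acsl6 in 8 and 4, for both genes among them leaving out LHP tumors 2, 3 or 6 or S7HP tumors 9 or 12 in the first and S7HP tumors 11 or 12 in the second (limma, Benjamini-Hochberg adjusted p up to 0.143). Lrp8 was also lost without S7HP tumor 11 in the first comparison and without LHP tumor 3 or 6, S7HP tumor 9 or S7HP+Snail tumor 13 or 14 in the second. Of the 243 genes, which were picked for being called both ways, 221 were not called in S7HP+Snail against LHP. Over all 2702 genes called in S7HP against LHP, which were picked for that change, the median log2 change was 1.85 in size, and a median of 1.02 in the same direction remained in S7HP+Snail against LHP. Both comparisons use the S7HP tumors, which pushes fold changes to opposite signs by chance. Independent lists of these sizes would share 17.4 and 13.6 genes in the opposite directions. Across genes, which are not independent replicates, the fold changes correlated at r = -0.56, against -0.50 in 50 simulations of unchanged groups (-0.52 to -0.48). Their covariance was -0.85 against a simulated -0.17, a difference of -0.69. In an alternative chosen after seeing the data, the S7HP tumors were split, 1 used in one comparison and 2 in the other, so that no library was shared. Over the 6 such splits r lay between -0.48 and -0.30 and the covariance between -0.83 and -0.55 (mean -0.68). Each split left a lone tumor in 1 of the comparisons, taken to vary like the other groups. Counts of calls from the splits are therefore not used as evidence here. How many of the 243 come from the shared tumors was not measured. The simulated groups did not differ, whereas the real groups did. Genes whose level in S7HP differs from both other groups give opposite signs even when no library is shared. The simulations, the splits and the independent lists therefore do not show that Snail moved genes back toward LHP in particular. The count of 243 fell to 94, 53 and 74 without S7HP tumors 9, 11 and 12, to 128 and 121 without LHP tumors 3 and 6, and to 103 when each comparison was fitted on its own 6 libraries.

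**Figure D4:**
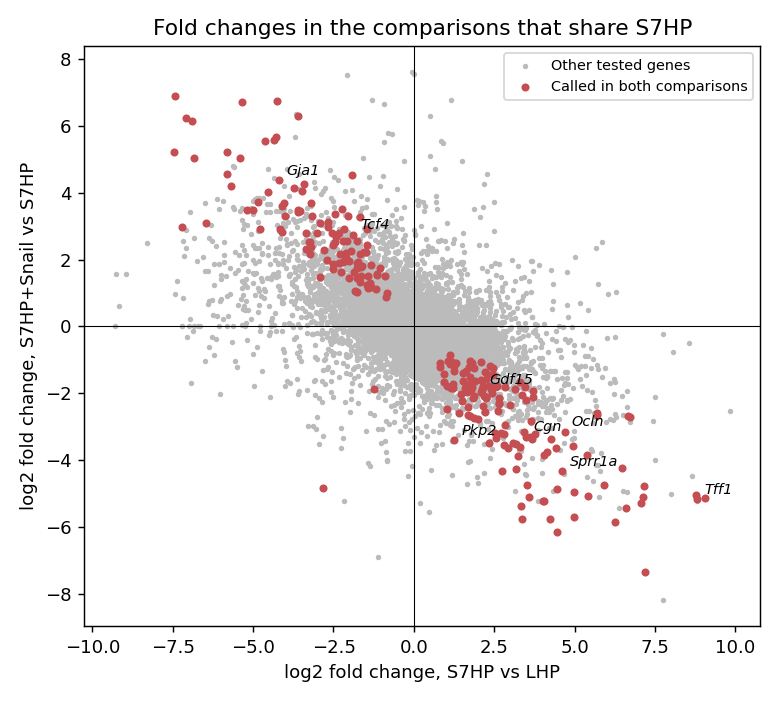
Log2 fold change of each tested gene in S7HP against LHP (horizontal) and in S7HP+Snail against S7HP (vertical), with genes called in both comparisons in red. Of the red genes, 243 lie in the quadrants of opposite sign and 2 in those of the same sign.

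The comparison of S7HP+Snail with LHP shows which differences from LHP were present with Snail added. Against LHP, 6 of 12 fetal liver genes and 10 of 22 interferon response genes rose, 1 fetal liver gene fell, and 9 of 25 matrix genes fell. The 3 lists passed limma camera with a preset correlation but not with an estimated one (Benjamini-Hochberg, adjusted p = 0.448 with an estimated correlation for each). Igf2, the fetal growth factor gene, rose by 8.38 ± 1.07 (SE), from 7.09 ± 1.05 to 15.47 ± 0.68 (SD, n = 3 each), and H19 rose by 7.01 ± 0.59. Tnnt2 fell by 6.60 ± 0.70, from 13.02 ± 0.54 to 6.42 ± 1.47. Adjusted p was 0.00345, 0.000773 and 0.00205 for these 3 genes (limma, Benjamini-Hochberg). Of 14215 genes, 1026 were called, 476 higher and 550 lower. Of the 2702 genes called in S7HP against LHP, 727 (26.9%) were called in the same direction here.

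Other large rises were in Apela (7.31), Calml4 (5.94), Enpp2 (5.59), the progenitor marker Prom1 (5.41), Dlk1 (5.41) and Afp (5.38). Apela was listed at 0 in 1 LHP tumor. The remaining falls were in the lectin-like receptor genes Klra4 (-6.11), Klra18 (-6.11) and Klrc1 (-5.21), the growth factor Areg (-5.53), Map2 (-5.02), Ggct (-4.92) and Fbln2 (-4.68). Klra4 and Klra18 are near-identical copies whose reads may be split between them, so neither is certain by itself. Afp was lost without LHP tumor 3 (0.0594), Areg without LHP tumor 2, 3 or 6 (up to 0.084), Dlk1 without LHP tumor 2 or 6 or S7HP+Snail tumor 13 or 14 (up to 0.0931), and Klrc1 without any 1 LHP or S7HP tumor (up to 0.14), as adjusted p (limma, Benjamini-Hochberg). Klrc1 was at 1.96 in S7HP+Snail tumor 15, against 7.57 and 7.68 in tumors 13 and 14, and its log2 change without tumor 15 was -3.32.

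Of 22 interferon response genes, 10 rose, 0 fell and 12 did not pass (13 rose when adjusted over the list alone), including Ifi44 (2.71), Isg15 (2.58) and Usp18 (3.37), at a Benjamini-Hochberg adjusted p of 2.41e-09 (limma camera; adjusted p = 0.448 with an estimated correlation). Of 12 fetal liver genes, 6 rose and 1 fell (6 and 2 when adjusted over the list alone), at a Benjamini-Hochberg adjusted p of 0.0234 (limma camera; adjusted p = 0.448 with an estimated correlation). Of 25 hepatocyte genes, 5 rose and 0 fell (6 rose when adjusted over the list alone), among them albumin, Alb (2.49), at a Benjamini-Hochberg adjusted p of 0.00148 (limma camera; adjusted p = 0.815 with an estimated correlation). Of 25 matrix genes, 9 fell and 0 rose (17 fell and 1 rose when adjusted over the list alone), including Col1a1 (-2.60) and the crosslinking enzyme Lox (-2.89), at a Benjamini-Hochberg adjusted p of 2.3e-08 (limma camera; adjusted p = 0.448 with an estimated correlation). Alongside, 3 of 17 stellate and fibroblast markers fell and 0 rose (6 fell and 1 rose when adjusted over the list alone), at a Benjamini-Hochberg adjusted p of 0.00291 (limma camera; adjusted p = 0.448 with an estimated correlation). Of 20 mesenchymal genes, 4 fell and 0 rose (6 fell when adjusted over the list alone), including vimentin, Vim (-1.70), at a Benjamini-Hochberg adjusted p of 0.00392 (limma camera; adjusted p = 0.448 with an estimated correlation). The TGF-β target list was lower, with 4 of 25 members fallen, led by Pmepa1 (-3.97), and Bambi risen (1.97), or 8 and 1 when adjusted over the list alone, at a Benjamini-Hochberg adjusted p of 0.00715 (limma camera; adjusted p = 0.815 with an estimated correlation). Epithelial junction genes did not pass as a list, with 4 of 25 risen, Pkp2 fallen (-2.15) and the same counts when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.736). Of 30 cell cycle genes, 0 rose and E2f1 fell (-1.58), with the same counts when adjusted over the list alone, and the list was lower at a Benjamini-Hochberg adjusted p of 0.00245 (limma camera; adjusted p = 0.819 with an estimated correlation), at up to 0.0233 without 1 library. The call of E2f1 was lost without LHP tumor 3 or 6 (limma, Benjamini-Hochberg adjusted p up to 0.0674). The glycolysis and hypoxia list was lower with 0 of 22 members called by limma (2 lower at an unadjusted p under 0.05), and the fatty acid oxidation list and the bile acid and xenobiotic list were higher with 1 of 20 and 4 of 19 risen (0 lower, 1 higher and 6 higher when adjusted over each list alone), at Benjamini-Hochberg adjusted p of 0.00245, 0.0234 and 0.00278 (limma camera; adjusted p = 0.815, adjusted p = 0.819 and adjusted p = 0.815 with an estimated correlation). Without S7HP+Snail tumor 14 none of these 3 lists passed (0.336, 0.317 and 0.111), and the fatty acid oxidation list also did not pass without LHP tumor 2. The erythroid list was higher with 1 of 7 members risen and 0 fallen (the same when adjusted over the list alone), and the MHC class II list was lower with 0 of 8 members called by limma, also over the list alone (5 lower at an unadjusted p under 0.05). Their Benjamini-Hochberg adjusted p was 0.0269 and 0.0192 (limma camera; adjusted p = 0.815 with an estimated correlation for each). The erythroid list no longer passed without LHP tumor 6 or S7HP+Snail tumor 15 (up to 0.254), nor the MHC class II list without LHP tumor 6 or S7HP+Snail tumor 13 or 15 (up to 0.115). Without LHP tumor 2, 3 or 6 the calls of Alb, Lox, Vim and Bambi were lost, that of Vim also without S7HP+Snail tumor 13 or 14 and that of Bambi also without 15, with adjusted p up to 0.113 (limma, Benjamini-Hochberg). The fetal list no longer passed without LHP tumor 2 or S7HP+Snail tumor 13 (up to 0.113). The count of 1026 fell to 452, 293 and 311 without LHP tumors 2, 3 and 6, and to 682 when only the 6 libraries compared were fitted. More genes were higher than lower without an LHP tumor, with 229 and 223, 150 and 143, and 173 and 138 without tumors 2, 3 and 6. The groups did not overlap for 30.5% of the genes, against a chance share of 10%.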

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

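All alternatives were planned except a pseudocount of 16, a fit without the intensity trend, library quality weights and splits of the S7HP tumors between the comparisons, which were chosen after seeing the data. Library size alone, a prior count of 2, limma voom and a Wald test on counts were planned and not run, since they need raw counts, and median-of-ratios scaling was applied to the unlogged values. No paired analysis was possible because the groups share no tumor numbers. Under scaling, filters, variance models, weights and the pseudocount, the counts of called genes and of opposite calls stayed within 1.5 times their values. Fitting only the libraries compared gave 3430 genes for S7HP against LHP, 120 for S7HP+Snail against S7HP, 682 for S7HP+Snail against LHP and 103 opposite calls. Leaving out 1 library at a time gave 1465 to 3163 genes for S7HP against LHP, 63 to 451 for S7HP+Snail against S7HP, 293 to 1049 for S7HP+Snail against LHP and 53 to 300 opposite calls, and leaving out a library also lowers the residual degrees of freedom. The fold correlation of -0.56 was -0.53 with no filter, -0.57 with a pseudocount of 16 and between -0.61 and -0.52 without 1 library, against a spread taken from the simulations. With the S7HP tumors split, opposite calls numbered 62, 42 and 33 (fold correlations -0.30, -0.43 and -0.48) where tumor 9, 11 or 12 alone was set against LHP and the other tumors against S7HP+Snail, and 17, 20 and 0 (-0.48, -0.36 and -0.30) in the reverse use. Each split left a lone S7HP tumor in 1 of the comparisons, taken to vary like the other groups. The counts of opposite calls from the splits therefore support no conclusion. Of the named calls, 76 of 101 in S7HP against LHP, 8 of 33 in S7HP+Snail against S7HP and 35 of 81 in S7HP+Snail against LHP were kept without any 1 library. Of the 44 list calls made with the preset correlation, 44 were lost with an estimated correlation, and with fry 10 of 17, 0 of 13 and 5 of 14 held in the 3 comparisons. Depth limits genes near 3 reads, and changes of 1 on the log2 scale were called in 4% of simulated genes. That simulation changed 200 genes, far fewer than the 2702 called in S7HP against LHP, so its shares do not give the power there.

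The direction of 32 results turned under at least 1 alternative, none of them passing the test where it turned, and the cause was not tested. A single one passed otherwise, the urea and amino acid list in S7HP+Snail against S7HP (lower, limma camera, Benjamini-Hochberg adjusted p = 0.0475; adjusted p = 0.862 with an estimated correlation), which turned higher at 0.992 without S7HP tumor 9, in a leave-one-out range of 0.000296 to 0.992. Among genes, log2 changes without 1 library ran from -0.26 to 0.03 for Trp53 and from -0.24 to 0.87 for Cyp2e1 (-0.19 with library weights) in S7HP against LHP. They ran from -0.52 to 0.14 for Hras in S7HP+Snail against LHP, and in S7HP+Snail against S7HP from -1.22 to 0.23 for Alas2, -0.22 to 1.32 for Csf3r and -1.67 to 0.18 for Retnlg. Lists that turned are given by the range of their adjusted p (limma camera, Benjamini-Hochberg) without 1 library. In S7HP against LHP these were B and plasma cell (0.583 to 0.997), cholesterol synthesis (0.486 to 0.957), glycolysis (0.592 to 0.983), neutrophil (0.486 to 0.984) and stress genes (0.396 to 0.915). In S7HP+Snail against S7HP they were B and plasma cell (0.38 to 0.992), MHC class II (0.0165 to 0.937), RAS output (0.259 to 0.918), apoptosis (0.542 to 0.937), bile acid and xenobiotic (0.0675 to 0.877), cell cycle (0.00116 to 0.631), erythroid (0.218 to 0.986), fetal liver (0.48 to 0.952), inflammation (0.171 to 0.937) and neutrophil genes (0.169 to 0.889). In S7HP+Snail against LHP they were B and plasma cell (0.438 to 0.957), T and NK cell (0.00284 to 0.894), TGF-β component (0.336 to 0.957), apoptosis (0.8 to 0.915), endothelial (0.322 to 0.877), epithelial (0.134 to 0.877), inflammation (0.644 to 0.999), neutrophil (0.284 to 0.917), p53 target (0.74 to 0.976) and stress genes (0.243 to 0.908). Other settings turned the neutrophil list in S7HP against LHP (0.707 with no filter), the B and plasma cell list there (0.874 with fry and 0.996 with only the 2 groups fitted), and in S7HP+Snail against LHP the p53 target list (0.949 with no filter, 0.996 with the stricter filter, 0.981 with the pseudocount and 0.974 with only the 2 groups fitted), the inflammation and neutrophil lists (0.949 each with no filter) and the T and NK cell list (0.811 with the stricter filter).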

Other observations

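The tests of explanations in this part were chosen after the results were seen, and what the counts of splits would show was also written down after those counts were known. Of 19 fatty acid synthesis and storage genes, 7 rose, 2 fell and 10 did not pass in S7HP against LHP (7 and 3 when adjusted over the list alone), led by the droplet protein Cidec at 6.62 ± 0.48 (SE) and the triglyceride enzyme Dgat2 at 3.15 ± 0.30 (limma, Benjamini-Hochberg adjusted p = 0.00013 and 0.00059). Cidec was at 1.22, 2.26 and 1.22 in the LHP tumors, near the level of 3 reads, and its change was 4.08 with a pseudocount of 16. The list itself did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.177, and adjusted p = 0.644 with an estimated correlation). With Snail added, Dgat2 fell by 1.87 ± 0.30 relative to S7HP (limma, Benjamini-Hochberg adjusted p = 0.0178), and that call was lost without S7HP tumor 9, 11 or 12 (up to 0.0728). Cholesterol synthesis genes were lower in S7HP+Snail than in LHP, with 4 of 20 fallen and 0 risen (6 fallen when adjusted over the list alone), including Idi1 (-1.37) and Sqle (-1.56), at a Benjamini-Hochberg adjusted p of 0.0135 (limma camera; adjusted p = 0.815 with an estimated correlation). That list no longer passed without S7HP+Snail tumor 14 (0.065), Idi1 was lost without LHP tumor 2, 3 or 6 (up to 0.065), and Sqle without any 1 LHP or S7HP+Snail tumor (up to 0.117).

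The inflammation list and the B and plasma cell list did not pass in S7HP against LHP (limma camera, Benjamini-Hochberg adjusted p = 0.691 and 0.962) or in S7HP+Snail against LHP (0.959 and 0.86), while single members did. Cxcl5, a neutrophil-attracting chemokine, rose by 3.71 ± 0.81 (SE) in S7HP and by 5.37 ± 0.81 in S7HP+Snail (limma, Benjamini-Hochberg adjusted p = 0.0128 and 0.0068), while 0 of 9 tested neutrophil markers passed with limma in S7HP against LHP (1 higher and 2 lower at an unadjusted p under 0.05, list median 0.86 and mean -0.34). The rise of Cxcl5 in S7HP was lost without LHP tumor 3 (0.0538). The acute phase genes Saa1 (-2.43) and Saa2 (-2.95), which are near-identical copies, fell in S7HP+Snail. Of the 12 members of the B and plasma cell list, 4 were tested. The immunoglobulin chain gene Jchain fell in S7HP (-4.02) and in S7HP+Snail (-5.81). Mzb1, on the same list, fell in S7HP+Snail (-4.49), a call lost in 12 of 17 alternatives. Xbp1, a transcription factor on that list, rose in both (1.27 and 1.35). In S7HP+Snail, Saa1 and Jchain were lost without LHP tumor 2 or 6 (up to 0.109 and 0.0738), and Saa2 without LHP tumor 2, 3 or 6 or S7HP tumor 11 (up to 0.117). In S7HP, Jchain was lost without LHP tumor 2 or 6 or S7HP tumor 11 or 12 (up to 0.134). Of the p53 target list, 3 of 22 rose and 2 fell in S7HP (4 and 2 when adjusted over the list alone), with Gdf15 at 2.11 and Zmat3 at -1.54, and the list did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.676).

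The mean of the hepatocyte list was higher in S7HP than in LHP by 1.68 ± 0.51 (SE over tumors). Normal adult liver mixed into the S7HP tumors would raise a transcript as much as Alb only if liver exceeds tumor cells as strongly for it. Those ratios were not measured. In a first test, 39 urea cycle, amino acid, bile acid and xenobiotic genes that lay below Alb in LHP were taken. Their mean change was smaller than that of Alb (difference -1.60 ± 0.41), although single members such as Gsta2 (4.46) rose more than Alb (2.72). Genes that tumor cells also express would rise less than Alb with admixed liver too, so the first test does not decide whether liver was admixed. A second version on Cyp2e1, Cyp3a11, Cyp2c29 and Cps1 (-1.55 ± 0.44) decides nothing, since these genes were picked after their values were seen. A fetal-type hepatocyte program in the tumor cells stays open, as does the engineered difference between the groups, and the fetal liver list mean, higher by 2.15 ± 0.34, was known beforehand and so does not test it.

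The means of the matrix list and of the fibroblast list were lower in S7HP. A lower share of all non-tumor cells would lower every such cell type alike. The macrophage and endothelial list means did differ by similar amounts, -0.85 ± 0.21 and -0.81 ± 0.39 (SE over tumors). The stellate and fibroblast list mean differed by -1.44 ± 0.29. The matrix list, which is not a cell type, differed by -2.34 ± 0.28, a gap of -1.49 ± 0.36 from the macrophage list. A lower share of fibroblasts alone would lower matrix genes and fibroblast markers alike, and the gap there was -0.90 ± 0.32. The first gap argues against an equal loss of all non-tumor cells as the whole cause of the matrix fall, though not as a part of it. The second argues against a loss of fibroblasts alone. Both hold only as long as other cells add little to those markers, which was not tested. The fibroblast markers did not fall alike, with an SD of 1.29 across their changes against a mean SE of 0.61. The second gap thus depends on which markers are listed. Losses of several cell types at different rates were not tested. Fibroblasts or tumor cells making less matrix in tumors labelled for Smad7, a label that the measured values do not check, may add to the fall. No test here separates those sources.

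Smad7 and Snai1 were lowest in S7HP. An exchange of the LHP and S7HP labels would put the lower TGF-β target values in the libraries labelled LHP, but the target list was lower in those labelled S7HP by 1.10 ± 0.27 (SE over tumors; difference -1.10). Construct reads that lack the mouse 3′ end may be missing from both genes. Missing reads could leave the constructs unseen, but could not by themselves put Smad7 below LHP, at -3.55. With 0 reporter symbols listed, no value here decides whether construct reads were missed.

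With 3 tumors against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05, and 1 split, the real one, gave as many calls in each comparison. The real split gave 2702 genes for S7HP against LHP (highest other 0), 327 for S7HP+Snail against S7HP (highest other 1) and 1026 for S7HP+Snail against LHP (highest other 0).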
